A study of Rattus norvegicus with 9 samples.

How the data were processed

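Total RNA of cultured rat renal artery endothelial cells, the cells that line the artery supplying the kidney, was sequenced in 9 libraries. The labels place 3 libraries in each of 3 groups, named Normal, Model and a group treated with calycosin and tanshinone IIA, called the treated group here. Per the labels' protocols, RNA was extracted with a column kit and made into strand-specific total RNA libraries. CASAVA 1.8 and the genome build mRatBN7.2 are named in the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here, so lncRNAs that overlap a gene or lie antisense to one are uncertain.

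The authors deposited whole-number read counts in 2 tables, 1 of genes and 1 of lncRNA transcripts, per the file headers. The same tables hold FPKM values (fragment counts scaled to transcript length and depth) that the authors computed, per the file headers. The gene table lists 32883 Ensembl rat gene identifiers, of which 12736 were at 0 in all 9 libraries. The lncRNA table lists 16814 transcripts, all above 0 in at least 1 library: 14394 with NONCODE catalogue numbers (NONRATT), 1632 with assembled-locus numbers (MSTRG) and 788 Ensembl transcripts. Within each table, count divided by FPKM differed between libraries by 1 constant factor to within 0.00181%, so each feature compared has a single length. Only values above a minimum count were compared, and features with lower counts were not checked. In the gene table that factor followed the library's total count. In the lncRNA table it was 0.980 to 1.08 times what the total of that table gives, so another total was used there. The counts entered all tests, and the deposited FPKM values served to recover gene lengths.

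In units of 1e6 counts, library totals were 7.98 to 18.3 in the gene table and 0.711 to 1.58 in the lncRNA table. At these depths 3 counts correspond to 0.164 to 0.376 counts per 1e6 counts of the library (CPM) for a gene and to 1.89 to 4.22 CPM for a lncRNA. The typical variation between replicates (biological coefficient of variation, edgeR common dispersion) was 8.87% for genes and 34.7% for lncRNAs. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Replicate pairs were compared by a chi-square statistic of their counts, which was 4.77 to 15.1 per degree of freedom for genes and 7.01 to 10.4 for lncRNAs, so no pair agreed within sampling noise and each library counts as 1 replicate.

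Each table was tested on its own with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, estimateDisp and glmQLFit with robust settings, glmQLFTest). All 9 libraries entered 1 fit with the group as the only term. The filter kept 12943 genes, which hold 99.9% of the gene counts, and 8653 lncRNAs, which hold 97.8% of the lncRNA counts. A feature was called at a Benjamini-Hochberg adjusted p below 0.05 within its table, with no minimum fold change. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The groups, comparisons, tests and alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter or a stricter one, fits on 2 groups only, a replicate block, a fold minimum, an unadjusted threshold, a fit without robust settings and leaving out each library. Thinning to equal depth, removal of a gene-length trend, leaving out jumping lncRNAs, a within-group component and a surrogate variable from sva 3.50.0 were added after the data were seen.

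The fit was tested on simulated data first, drawn from the real means, library sizes and dispersions with 200 features changed, in 3 draws per comparison. For Model against Normal, 68.7% of genes changed 1.5-fold, 87.1% of genes changed 2-fold and 95.5% of genes changed 4-fold were recovered among 12943, and 5.82% of the calls were false. For the treated group against Model the shares were 67.2%, 84.6% and 93.4%, with 7.20% false, and for the treated group against Normal 63.2%, 84.1% and 96.0%, with 5.26% false. Among 8653 lncRNAs, 5.47% of 2-fold changes and 66.7% of 4-fold changes were recovered for Model against Normal with 10.6% false calls, 4.98% and 57.6% for the treated group against Model with 6.02% false, and 5.47% and 54.5% for the treated group against Normal with 5.51% false.

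The gene table pairs its identifiers with no symbols. The reference gene table used for names (GRCr8 assembly, 47357 genes) holds 0 Ensembl identifiers, so none of the 32883 identifiers could be matched, which says nothing about the identifiers themselves. The 28 gene lists fixed before the data were examined (659 symbols) could therefore not be scored, and single genes known by symbol were not analysed here. A test of lncRNAs against neighbouring genes needs positions and was not run. Features named in the text follow a rule fixed before the data were examined: among called features with a mean level at or above the median of tested features and no overlap between the libraries of the groups, those with the most positive and most negative log2 fold change. The rule names 4 lncRNAs in each direction. For genes it asked for 8 with a symbol in each direction, or the 5 with the smallest p where no gene was called. Its condition on symbols could not be applied, and because bare identifiers say little, the first 2 in each direction are given per comparison. MSTRG.7363.2 and NONRATT004982.2 were named after their values were seen. Figures were drawn with matplotlib 3.10.9.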

Results

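The series title sets the question: whether calycosin, an isoflavone, and tanshinone IIA, a diterpene quinone of the danshen root, together change the response of renal artery endothelial cells to angiotensin II, the pressor peptide of the renin-angiotensin system. RNA of rat cells was measured as gene counts and as counts of lncRNA transcripts, that is, long RNAs with no known protein product. The libraries fell into a Normal group, a Model group, which the title ties to angiotensin II, and a group treated with both compounds, with 3 libraries each. Doses and times are not stated in the labels.

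In units of 1e6 counts, the gene table totalled 13.5, 13.6 and 12.3 in the Normal libraries, 13.2, 15.9 and 17.2 in the Model libraries and 18.3, 7.98 and 8.15 in the treated libraries. The lncRNA counts equalled 8.37% to 9.28% of the gene counts. The 10 most abundant genes took 4.47% to 4.81% of a library's gene counts, and the 10 most abundant lncRNAs 19.4% to 23.0% of its lncRNA counts. Across genes, log2 CPM of replicates correlated with a mean r of 0.989 in Normal, 0.987 in Model and 0.989 in the treated group, and Model and Normal libraries correlated with a mean r of 0.986. Model and treated libraries correlated across genes with a mean r of 0.987, and Normal and treated libraries with 0.982. Across lncRNAs the mean r within a group was 0.865 to 0.881. Between groups it was 0.882 for Normal and Model, 0.869 for Normal and treated and 0.868 for Model and treated. Replicates were thus no more alike across lncRNAs than Normal and Model libraries were. Genes and lncRNAs are not independent replicates in these correlations. The first principal component of the gene table held 36.2% of the variance. Normal libraries had scores of -28.4, -20.8 and -10.4 on it and treated libraries 13.2, 20.3 and 20.5, while Model libraries spread from -17.4 to 16.8. In the lncRNA table the first component held 15.5% of the variance and split the treated group. Treated libraries 2 and 3 scored 33.2 and 43.3, treated library 1 -1.02, and Normal and Model libraries -25.6 to -2.56. Treated libraries 2 and 3 also had the smallest lncRNA totals, 0.711 and 0.756 in units of 1e6 counts, so depth and treatment are not separated there.

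**Figure D1:**
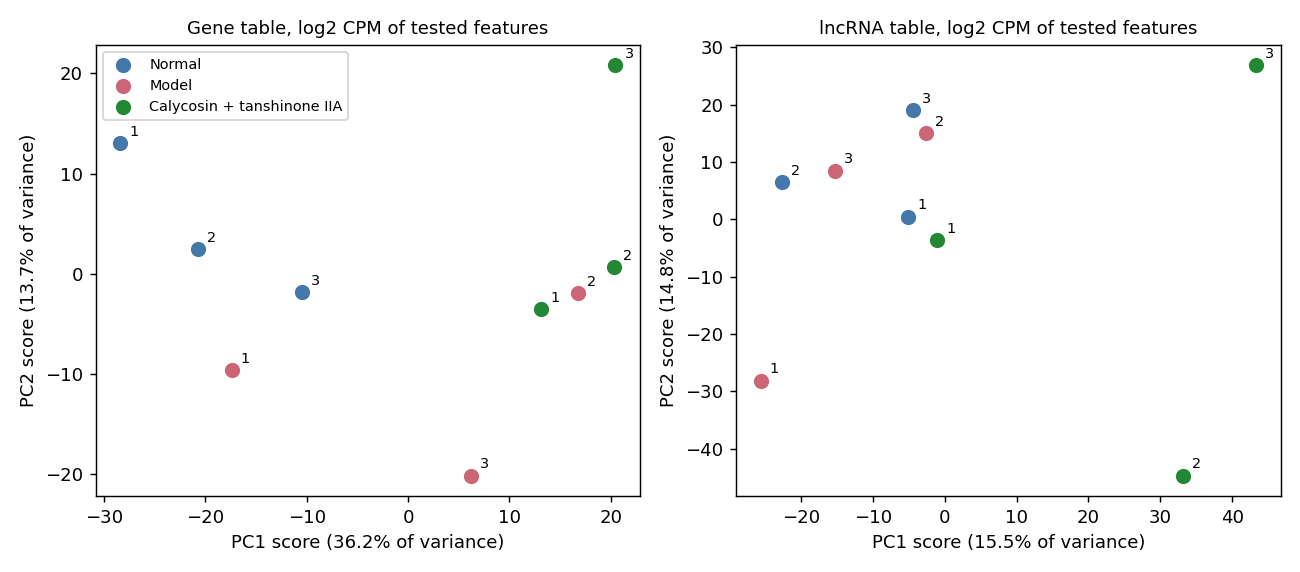
Scores of the 9 libraries on the first principal components of log2 CPM (x axis: PC1, y axis: PC2), for tested genes on the left and tested lncRNAs on the right; each point is a library, numbered by replicate. On PC1 of the gene table, which holds 36.2% of the variance, Normal libraries lie on the negative side, treated libraries on the positive side, and Model libraries on both. On PC1 of the lncRNA table, which holds 15.5%, treated libraries 2 and 3 lie apart from all others, and treated library 1 does not.

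Model against Normal asks what the Model condition changed. Among lncRNAs, 5 of 8653 tested were called, 2 higher and 3 lower in Model. At an unadjusted edgeR p below 0.05 there were 331 lncRNAs, where 433 are expected by chance. Another grouping of these libraries, Normal 1, Normal 3 and Model 3 against the rest, also called 5. NONRATT007758.2 rose from 2.62 ± 0.087 CPM in Normal, which is 3 counts in each library, to 120.2 ± 9.63 CPM in Model (SD, n = 3), a log2 fold change of 5.46 ± 0.31 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.66e-05). The transcript with the next lower catalogue number, NONRATT007757.2, went the other way, from 306.4 ± 15.5 to 13.3 ± 4.54 CPM (log2 fold change -4.53 ± 0.24, edgeR adjusted p = 1.66e-05). NONRATT005775.2 fell from 552.2 ± 52.5 to 47.9 ± 15.9 CPM (log2 fold change -3.53 ± 0.22, edgeR adjusted p = 4.86e-05), and NONRATT004982.2 from 54.7 ± 4.94 to 3.70 ± 0.996 CPM (log2 fold change -3.88 ± 0.29, edgeR adjusted p = 0.000129), which is 5, 4 and 5 counts in Model. MSTRG.7363.2 had 0 counts in all 3 Normal libraries and 41, 35 and 54 counts in the Model libraries, at least 38.3-fold higher when 3 counts over the Normal group are taken as the floor (edgeR adjusted p = 0.00187). MSTRG.7363.5, another transcript of that assembled locus, was at 502.9 ± 47.4 CPM in Normal and 279.4 ± 43.2 CPM in Model and missed the threshold (edgeR adjusted p = 0.0532).

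The lncRNA count of 5 became 8 without Normal 1, 9 without Normal 2, 16 without Model 1, 8 without Model 2 and 9 without treated library 1, and the 5 called lncRNAs stayed called in each of these fits. It was 13 in DESeq2 and 11 in a fit on these 2 groups alone. It fell to 1, with none of the 5 among the tested transcripts, when lncRNAs that jump at least 4-fold between a low and a high set of libraries were left out, a set that by its definition holds the largest changes.

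No gene passed the threshold between Model and Normal: 0 of 12943 were called by edgeR, with a smallest adjusted p of 0.999, and 0 by DESeq2. At an unadjusted p below 0.05 there were 550 genes in edgeR, where 647 are expected by chance, and 333 in DESeq2. The genes with the smallest p were ENSRNOG00000040215, at 2.83 ± 0.832 CPM in Normal and 0.941 ± 0.364 CPM in Model (log2 fold change -1.61 ± 0.31), and ENSRNOG00000057072, at 2.56 ± 1.26 and 0.751 ± 0.412 CPM (-1.81 ± 0.41), among those lower in Model. Among those higher, ENSRNOG00000049740 was at 11.4 ± 0.818 and 15.8 ± 1.48 CPM (0.47 ± 0.11), and ENSRNOG00000024312 at 6.38 ± 1.07 and 10.3 ± 1.61 CPM (0.70 ± 0.17). Each of these 4 had an edgeR adjusted p of 0.999. In simulated libraries of the same depth and spread, 87.1% of genes changed 2-fold between Model and Normal were recovered. There 200 genes were changed 1.5-, 2- or 4-fold and each gene was drawn independently. With fewer changed genes the adjusted threshold is stricter, so this share does not show that 2-fold changes would have been found here. Leaving out Model 1 gave 16 genes, all lower in Model and ENSRNOG00000040215 among them (edgeR adjusted p = 0.0420), and leaving out Normal 1, Model 2 or Model 3 gave 1 gene each. With the first component of the within-group spread as a covariate, added after the data were seen, 47 genes were called, 2 higher and 45 lower in Model, ENSRNOG00000040215 and ENSRNOG00000057072 among them (edgeR adjusted p = 0.00616 and 0.0101). Such fits called at most 5 genes in simulated unchanged groups. Genes there were drawn independently, while the component held 26.6% of the within-group spread in the real counts. The simulation therefore cannot vouch for the 47 calls. Another grouping of these 6 libraries, Normal 1, Normal 3 and Model 2 against Normal 2, Model 1 and Model 3, called 354 genes.

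The treated group is set against Model on the assumption, taken from the series title, that its cells also received the Model condition; the labels name only the compounds. NONRATT019335.2 fell from 265.7 ± 41.6 CPM in Model to 4.50 ± 2.25 CPM in the treated group (log2 fold change -5.96 ± 0.30, edgeR adjusted p = 6.45e-06), which is 4, 5 and 3 counts. NONRATT000843.2 fell from 52.3 ± 8.82 to 2.49 ± 1.78 CPM (-4.56 ± 0.47, edgeR adjusted p = 0.00242), which is 1, 3 and 2 counts. The log2 fold change of NONRATT000843.2 was -3.90 without treated library 1 and -5.16 without treated library 2. Both were at levels in Normal, 258.7 ± 40.4 and 54.6 ± 16.1 CPM, that did not differ detectably from Model. NONRATT007758.2 fell from 120.2 to 3.82 ± 1.83 CPM (-5.06 ± 0.30, edgeR adjusted p = 2.21e-05), while NONRATT007757.2 rose to 341.9 ± 59.1 CPM (4.69 ± 0.24, edgeR adjusted p = 6.45e-06) and NONRATT005775.2 to 459.6 ± 52.1 CPM (3.27 ± 0.21, edgeR adjusted p = 6.98e-05). Less firm were a fall of NONRATT025640.2 from 49.3 ± 23.9 to 4.22 ± 0.292 CPM (-3.50 ± 0.46, edgeR adjusted p = 0.0140), whose adjusted p rose to 0.0817, 0.134 and 0.132 without treated library 1, 2 or 3, and a 1.49-fold rise of NONRATT010790.2 from 1110 ± 39.1 to 1650 ± 67.2 CPM (0.57 ± 0.08, edgeR adjusted p = 0.0140), whose adjusted p was 0.0527, 0.0697, 0.0618 and 0.0763 without Model 2, Model 3, treated library 2 or treated library 3. The adjusted p of NONRATT010790.2 was also 0.0685 with no count filter and 0.0610 without robust settings, and that of NONRATT025640.2 was 0.0541 without robust settings.

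In all, 11 lncRNAs were called between the treated group and Model, 3 higher and 8 lower. DESeq2 called 34, of which 15 were higher and 19 lower, and a fit on these 2 groups alone called 19, of which 8 were higher and 11 lower. The count was 19 without Model 1 and 18 without treated library 1, and it fell to 5 when lncRNAs that jump between a low and a high set of libraries were left out.

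**Figure D2:**
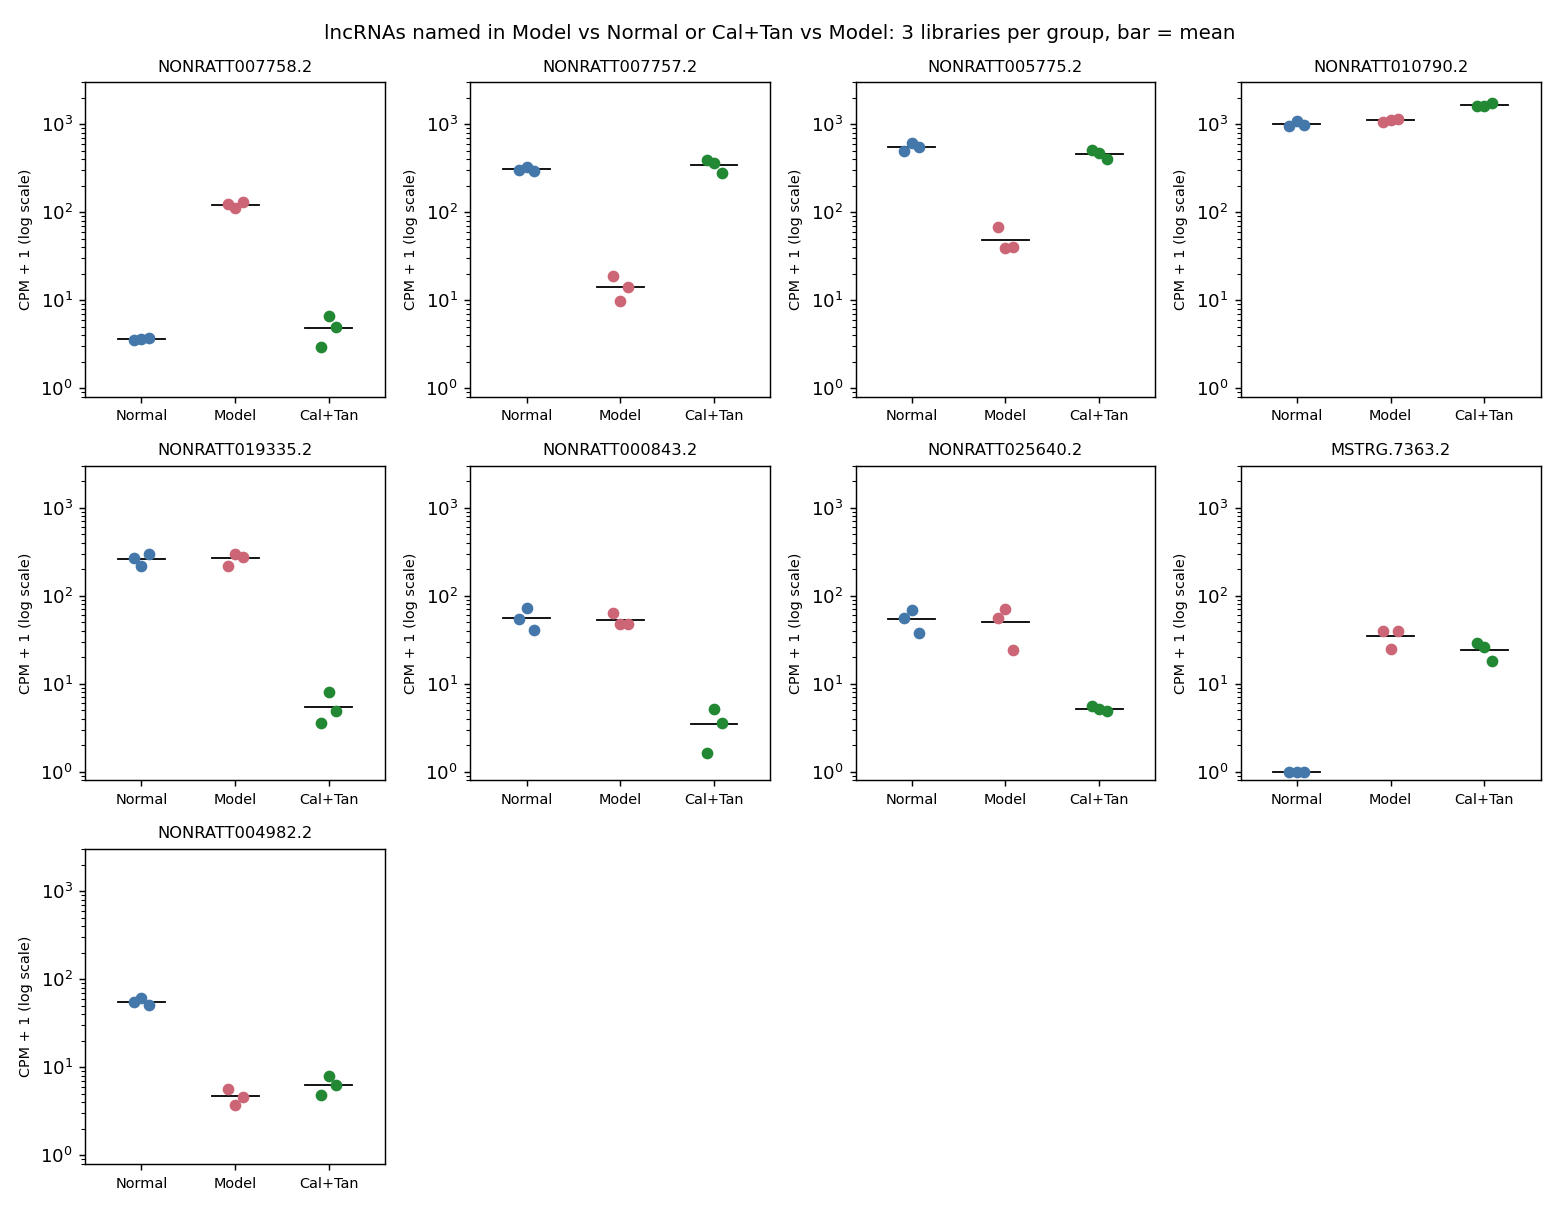
CPM + 1 on a log axis (y) in the Normal, Model and treated (Cal+Tan) groups for the 9 lncRNAs named in Model against Normal or treated against Model; each point is a library and the bar is the mean of 3. NONRATT007758.2 is high in Model alone, NONRATT007757.2 and NONRATT005775.2 are low in Model alone, and NONRATT019335.2 falls to 4.50 CPM in the treated group.

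Gene-level differences between the treated group and Model were small. Of 12943 genes tested, 119 were called, 74 higher and 45 lower in the treated group, with a median fold of 1.37, and 6 of them, all higher, changed at least 2-fold. ENSRNOG00000010819 rose from 27.0 ± 3.49 to 43.9 ± 3.25 CPM (log2 fold change 0.69 ± 0.11, edgeR adjusted p = 0.00874) and ENSRNOG00000014387 from 27.6 ± 3.41 to 44.4 ± 4.84 CPM (0.69 ± 0.11, edgeR adjusted p = 0.00874). ENSRNOG00000014963 fell from 46.2 ± 4.13 to 29.7 ± 3.20 CPM (-0.62 ± 0.10, edgeR adjusted p = 0.0102) and ENSRNOG00000009872 from 50.2 ± 3.20 to 34.1 ± 1.88 CPM (-0.55 ± 0.08, edgeR adjusted p = 0.00874). Each of the 119 had treated libraries that did not overlap the Model libraries, which 18.8% of all tested genes had and 10% would have by chance. The same 4 genes missed the threshold without treated library 2, with edgeR adjusted p from 0.0652 to 0.0772. All but ENSRNOG00000014387 also missed it without Model 3, and ENSRNOG00000014963 without Model 1 or treated library 3. With a surrogate variable ENSRNOG00000010819, ENSRNOG00000014963 and ENSRNOG00000009872 missed it too (edgeR adjusted p = 0.0653, 0.0715 and 0.0653).

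The number of genes called between the treated group and Model depended on single libraries and on covariates. It was 65 without Normal 1, 28 without Model 1, 215 without Model 2, 15 without Model 3, 56 without treated library 1, 8 without treated library 2 and 45 without treated library 3. DESeq2 called 203, which included 116 of the 119. Fits with a covariate added after the data were seen called 17 with a surrogate variable and 351 with the first component of the within-group spread.

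**Figure D3:**
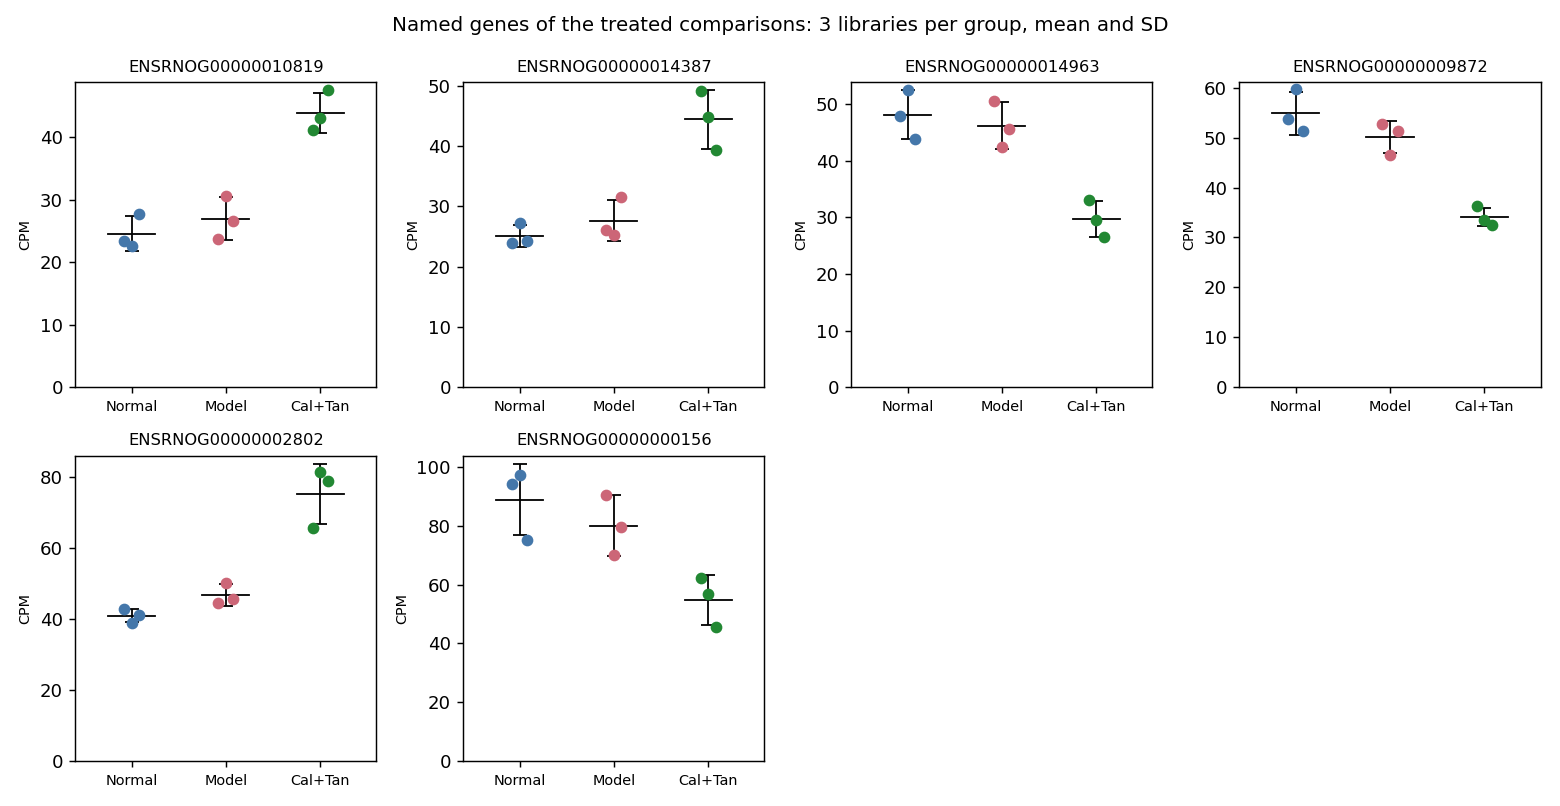
CPM (y axis, from 0) of the 6 genes named in the treated comparisons in the Normal, Model and treated (Cal+Tan) groups; points are libraries, and the line and bars are the mean and SD of 3. Normal and Model libraries overlap for 5 of these genes, and treated libraries lie apart from both groups for all 6.

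Features that moved in Model and back with treatment bear on the question in the title most directly, if the treated cells also received the Model condition. For lncRNAs there were 3: NONRATT007758.2 rose 44.1-fold in Model and fell 33.4-fold with treatment, folds that rest on 3, 3 and 3 counts in Normal and 3, 4 and 3 in the treated libraries, NONRATT007757.2 fell 23.1-fold and rose 25.8-fold, and NONRATT005775.2 fell 11.6-fold and rose 9.62-fold. In the treated group NONRATT007758.2 differed from Normal by a log2 fold change of 0.40 ± 0.39, NONRATT007757.2 by 0.16 ± 0.20 and NONRATT005775.2 by -0.26 ± 0.19, and none of the 3 was called there (edgeR adjusted p = 0.971, 0.939 and 0.845). The other 2 lncRNAs called in Model did not move back: MSTRG.7363.2 stayed at 23.3 ± 5.58 CPM and NONRATT004982.2 at 5.37 ± 1.55 CPM in the treated group. Both comparisons use the Model libraries, which favours opposite signs by chance. Simulated unchanged groups gave a mean of 0.1 such lncRNAs and at most 1 in 20 simulations, but called at most 2 lncRNAs in a comparison. Their counts were drawn around 1 mean per lncRNA and were not built to hold the jumps of at least 4-fold seen in real lncRNAs. They therefore measure neither chance jumps nor what the sharing adds. A jump that sets the Model libraries apart moves and returns by construction, and 3 lncRNAs had one. Trios of libraries other than the groups held a mean of 1.26 jumping lncRNAs and at most 4, so 3 lies within their range. Independent lists, which leave out the sharing, would hold 0.00185 up-then-down and 0.00104 down-then-up. The Model libraries are too few to be halved, so part of the excess over these values can come from sharing them. Chance jumps are not excluded either. The count was 11 without Model 1, 5 without Model 2, 5 without treated library 1 and 6 in DESeq2.

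For genes the count was 0, which follows from the 0 genes called in Model; it was 1 without Model 2 and 1 without Model 3. Of the 119 genes called between the treated group and Model, 32 had a Model against Normal fold change of the opposite sign and 87 of the same sign, although the latter did not pass the test in that comparison. Over all tested genes 46.9% had the same sign in both comparisons, against 34.2% in simulated unchanged libraries; neither is a no-change value for the 119, which were selected by their treated against Model change. ENSRNOG00000024312 was lower in the treated group than in Model (5.25 ± 1.15 against 10.3 ± 1.61 CPM, log2 fold change -0.93 ± 0.18, edgeR adjusted p = 0.0250) and nearer to Normal, at 6.38 CPM, but its difference between Model and Normal had an edgeR adjusted p of 0.999. Across genes, the covariance of the log2 fold changes was -0.00175, against a mean of -0.0208 and a range of -0.0300 to -0.0165 in 100 simulations, a difference of 0.0190. With a different Model library in each comparison the covariance averaged 0.0230, from -0.0105 to 0.0798 over 6 pairs of libraries. The correlation was -0.0282 across genes against -0.472 in simulated libraries. For lncRNAs the covariance was -0.121 against -0.130, a difference of 0.00897, and with a different Model library in each comparison it averaged 0.0147, from 0.00502 to 0.0302 over 6 pairs.

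**Figure D4:**
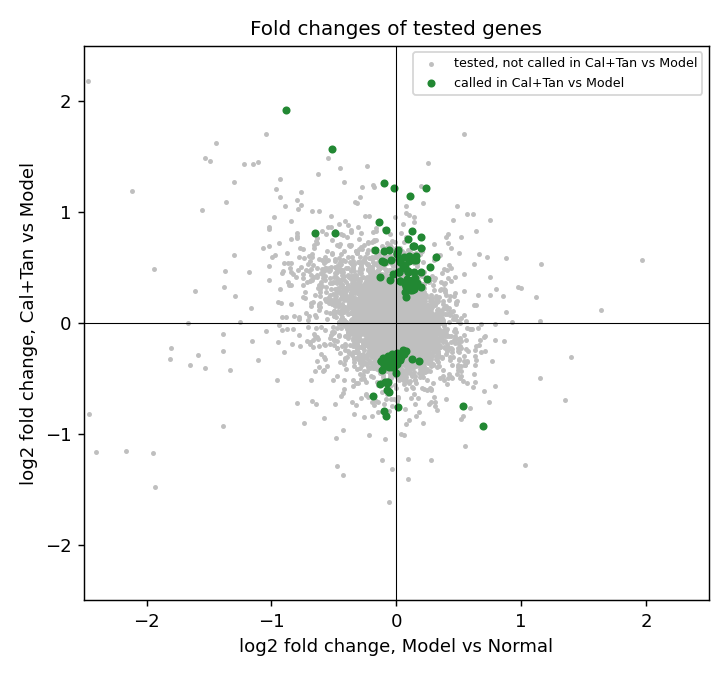
Log2 fold change of the treated group against Model (y axis) plotted against that of Model against Normal (x axis); each point is a tested gene, with the 119 genes called between treated and Model in green. Of 12943 genes, 46 lie outside the axes, none of them called; most called genes lie close to 0 on the x axis.

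The treated group against Normal gave the most gene calls. Of 12943 genes, 346 were called, 180 higher and 166 lower, with a median fold of 1.34, and 20 changed at least 2-fold, 9 higher and 11 lower. ENSRNOG00000002802 rose from 40.9 ± 1.87 CPM in Normal to 75.2 ± 8.41 CPM (log2 fold change 0.87 ± 0.09, edgeR adjusted p = 0.000286) and lay at 46.7 ± 3.05 CPM in Model. ENSRNOG00000010819 rose from 24.6 ± 2.76 CPM (0.83 ± 0.11, edgeR adjusted p = 0.00110). ENSRNOG00000014963 fell from 48.1 ± 4.34 CPM (-0.69 ± 0.10, edgeR adjusted p = 0.00256), and ENSRNOG00000000156 from 88.9 ± 12.1 to 54.9 ± 8.57 CPM (-0.69 ± 0.13, edgeR adjusted p = 0.0195). The last had an adjusted p of 0.0920 without Normal 1, 0.108 without Normal 2, 0.0833 without treated library 2 and 0.0654 without treated library 3, and of 0.0525 with a surrogate variable and 0.0617 with a length trend removed. The count of 346 was 98 without Normal 1, 181 without Normal 2, 671 without Normal 3, 94 without treated library 2 and 137 without treated library 3, and it was 182 with the surrogate variable and 930 with the within-group component as a covariate.

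Among lncRNAs, 16 were called between the treated group and Normal, 7 higher and 9 lower. The largest rise was that of MSTRG.7363.2, from 0 counts in Normal to 23.3 ± 5.58 CPM, at least 28.7-fold (edgeR adjusted p = 0.00295), and NONRATT004982.2 fell 10.5-fold (-3.39 ± 0.29, edgeR adjusted p = 0.000965). That fall rests on 6, 5 and 4 counts in the treated libraries. The 4 rises named by the fixed rule were of abundant transcripts and under 2-fold. NONRATT000217.2 rose from 4087 ± 159.3 to 6914 ± 499.5 CPM (log2 fold change 0.76 ± 0.07), NONRATT010790.2 from 1005 ± 76.6 to 1650 CPM (0.72 ± 0.08) and NONRATT014858.2 from 2422 ± 216 to 3952 ± 117 CPM (0.71 ± 0.07), all with an edgeR adjusted p of 0.00263. NONRATT010844.2 rose from 915.6 ± 43.7 to 1424 ± 131 CPM (0.64 ± 0.09, edgeR adjusted p = 0.0182), with an adjusted p of 0.0630 to 0.128 when Normal 1, 2 or 3, Model 3 or treated library 2 or 3 was left out and 0.0717 without robust settings. Of the falls, those of NONRATT019335.2 (-5.92 ± 0.30, edgeR adjusted p = 1.23e-05) and NONRATT000843.2 (-4.63 ± 0.47, edgeR adjusted p = 0.00263; -3.97 without treated library 1 and -5.23 without treated library 2) were close to those against Model. NONRATT025640.2 fell from 53.7 ± 16.1 CPM (-3.62 ± 0.46, edgeR adjusted p = 0.00689), with an adjusted p of 0.0688 to 0.0977 without treated library 1, 2 or 3. MSTRG.7363.5 fell from 502.9 to 220.8 ± 5.94 CPM (-1.19 ± 0.13, edgeR adjusted p = 0.00263). DESeq2 called 34 lncRNAs here.

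Of the 119 genes called against Model, 104 were also called against Normal with the same sign, 66 higher and 38 lower. Independent lists, which leave out that the treated libraries are used in both, would share 1.03 higher and 0.577 lower genes. Simulated unchanged groups gave a mean of 0.15 and at most 1, but called at most 5 genes in a comparison, so an overlap near 0 was set by the few calls and does not measure what the sharing adds. The covariance of the fold changes was 0.0556 across genes against 0.0246 in simulated libraries, a difference of 0.0310; the treated libraries are too few to be halved, so part of the overlap can come from sharing them. For lncRNAs, 8 of the 11 called against Model were also called against Normal with the same sign, 1 higher and 7 lower. Simulated unchanged groups gave a mean of 0.05 and at most 1, again with few calls, at most 2 in a comparison.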

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

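The fits on thinned counts, with a length trend removed, without jumping lncRNAs, with a within-group component and with a surrogate variable were chosen after seeing the data. Counts are given as Model against Normal, treated against Model and treated against Normal, with main values of 0, 119 and 346 genes and 5, 11 and 16 lncRNAs, and the cause of a shift was not tested unless stated. Upper-quartile factors, no count filter, a stricter filter, a fit without robust settings and thinning each left every count within 1.5 times its main value, as did the length correction, run for genes only, for the gene counts. DESeq2 gave 203 genes against Model and 13, 34 and 34 lncRNAs, with 6 lncRNAs moved back. Fits on 2 groups only gave 11 and 19 lncRNAs in the first comparisons. A minimum of 1 on the log2 scale left 6 and 20 genes in the treated comparisons, since most gene calls are smaller. It left 8 of the 16 lncRNAs called between the treated group and Normal. An unadjusted p of 0.05 with that minimum gave 48, 43 and 120 genes, 106, 133 and 153 lncRNAs, and 4 genes and 28 lncRNAs moved back. Without jumping lncRNAs 1 and 5 lncRNAs were called in the first comparisons and 0 moved back, because the called ones had been removed. With the first component of the within-group spread as a covariate the genes were 47, 351 and 930, and the covariate comes from the same counts. In 10 simulations of unchanged groups such fits called at most 5, 5 and 7. Those simulations drew genes independently and held no shared component, so they cannot vouch for the real calls. With a surrogate variable 17 and 182 genes were called in the treated comparisons, of which 17 and 177 were among the main calls. Leaving out 1 library gave 0 to 16, 8 to 215 and 94 to 671 genes, 5 to 16, 10 to 19 and 14 to 23 lncRNAs, and 0 to 1 genes and 3 to 11 lncRNAs moved back. The replicate block gave 1, 47 and 302 genes and 6, 11 and 17 lncRNAs, and ended the call of NONRATT010790.2 against Model (edgeR adjusted p = 0.0665). The values give no clear sign that replicate numbers pair the samples, and they cannot exclude it. Deviations of same-numbered libraries correlated above 0.1 in 2 of 9 pairs for genes (-0.0102 to 0.275) and 0 of 9 for lncRNAs. A library correlated best with its own number, among the 3 libraries of another group, in 7 of 18 comparisons for genes and 1 of 18 for lncRNAs. Named features kept their direction in all fits and thresholds tried. The outcome, called or not called, was the same in 599, the call was lost in 65 and gained in 5. The 599 include those in which the genes named in Model against Normal again missed the threshold. Some of the 65 come from the fold minimum. Scoring of gene lists, the test of lncRNAs against neighbouring genes and other pseudocounts were not run: the files pair genes with no symbols or positions, and the pseudocounts were planned for tests of normalized values. Log2 CPM for components and correlations used a prior count of 2 and the jumps CPM + 1, with no other value tried. Simulations at the depth and replicate spread of these libraries had 200 features changed. Of 2-fold changes between Model and Normal, they recovered 5.47% for lncRNAs and 87.1% for genes. Those shares hold for that number of changes, and the part of depth alone was not tested.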

Other observations

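The definition of jumping lncRNAs and the other gaps tried were set after the data were seen, as were the surrogate variable and the tests of neighbouring catalogue numbers, of the length trend in the 354 genes and of exchanged labels. The other tests here were written before their results were seen.

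A lncRNA was counted as jumping when its sorted log2(CPM + 1) values, with CPM taken over plain library totals, had a gap of at least 2 and its high libraries averaged at least 20 counts. This held for 603 of 16814 lncRNAs (3.59%) and for 20 of 12943 tested genes. These shares are not on a like basis. Genes had passed the count filter first, while all listed lncRNAs were examined. Gene libraries were also deeper, so the 1 added to CPM stands for more counts there. The definition held for 5 of the 5 lncRNAs called between Model and Normal, 8 of the 11 between the treated group and Model and 7 of the 16 between the treated group and Normal. That follows from the size of those changes and shows no separate kind of lncRNA. NONRATT005775.2 held 70, 56 and 54 counts in its low libraries. In 11 lncRNAs the jump fell exactly on a group, with the Normal libraries apart in 2, the Model libraries in 3 and the treated libraries in 6. Trios of libraries other than the groups held a mean of 1.26 and at most 4. The Normal and Model counts lie within that range, and the treated count lies above it.

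If the jumps of jumping lncRNAs fell on libraries at random, some would meet a group by chance; of the 280 ways to part 9 libraries into 3 trios, 1, the real one, held as many as 11, and the highest other held 10. At a 2-fold gap the groups held 11, as many came from 12 of the 280 ways and the highest other held 14; with the 4-fold gap and a mean of 50 counts the groups held 8 and 4 of the 280 ways held as many. These counts go against chance, but at a gap of 8-fold the groups held 5 and 43 of the 280 ways held as many, so the bound depends on the definition and chance is not excluded. Another candidate explanation is that the counting program moved reads between transcripts of a locus: for 176 jumping MSTRG transcripts the median correlation with the most abundant sibling was -0.505, against 0.00830 with unrelated transcripts (permutation p = 1e-04, the smallest that 10000 permutations can give), which that explanation needs. For NONRATT transcripts the median correlation with the adjacent catalogue number was -0.000449 (permutation p = 0.495), which leaves both open because catalogue numbers do not show a shared locus; the summed CPM of NONRATT007757.2 and NONRATT007758.2 was 309 in Normal, 133 in Model and 346 in the treated group, so a trade between them alone does not give both changes, and regulation by the Model condition or the compounds stays open too.

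The calls between the treated group and Model may come from library properties, since 2 treated libraries held far fewer gene counts than the other treated library (7.98 and 8.15 against 18.3 in units of 1e6). Thinning all libraries to the smallest total kept 92 of the 119 genes, with a median absolute log2 fold change of 0.44 against 0.46, so unequal depth alone does not account for the calls. Removing a length trend from each library kept 117 of the 119, so gene length does not account for them either. With a surrogate variable as a covariate 17 of the 119 stayed called. The variable was at 0.567 and 0.548 in the 2 shallow treated libraries and -0.444 in the deep one. In the other groups it also tended to fall as the total rose, from 0.0545 in Normal 3 (12.3 in the same units) to -0.330 in Model 3 (17.2). The median absolute log2 fold change was 0.45 against 0.46 and the median SE 0.09 against 0.08. In the median the fold thus changed little while the error widened. The covariate also takes up a degree of freedom, and its part in the lost calls was not tested. The loss of calls is therefore no evidence for a quality difference. A library property that goes with the total count was not separated from the treatment. RNA or library quality and an effect of the compounds stay open.

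The 6 Normal and Model libraries held a structure that their labels do not follow. Normal 1, Normal 3 and Model 2 against Normal 2, Model 1 and Model 3 called 354 genes, 344 of them lower in the latter 3 libraries, with a median length of 5126 nt against 2414 nt for all tested genes. A length trend between libraries is not the whole cause, since its removal left 88.4% of their median absolute log2 fold change (0.29 of 0.33), although 110 of the 354 calls were kept. An exchange of the labels of Normal 2 and Model 2 could give this split, but the lncRNA table called 2 in it, 5 with the labels as given and up to 5 in the others, too few to tell. On the first principal component of the gene table Normal 2 scored -20.8 and Model 2 scored 16.8, where treated libraries scored 13.2 to 20.5. An exchange would place a Normal library among the treated ones, which scores of single libraries do not exclude. RNA quality, culture differences and other batches stay open and were not tested; no biological explanation was tested.

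With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes the real split called 0, 119 and 346 in Model against Normal, treated against Model and treated against Normal, and the highest other split 354, 2 and 2; as many as the real one came from 10, 1 and 1 of the 10 splits. For lncRNAs the real split called 5, 11 and 16 and the highest other 5, 8 and 3; as many came from 2, 1 and 1 of the 10.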
